A study of Mus musculus with 4 samples.

How the data were processed

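Spleens of mice aged 10 weeks were dissociated, T cells were enriched, and γδ T cells were sorted as CD3-positive and TCRδ-positive cells that lacked TCRβ, B220 and CD11c, per the labels' protocols and the series design. Single cells were captured with a 10x Genomics 5′ kit, which tags each cDNA molecule with a cell barcode and a unique molecular identifier (UMI). Receptor transcripts were then amplified in 2 rounds with custom primers for the TCRγ and TCRδ constant regions and sequenced in 2 runs, per the labels' protocols. The submitters' processing notes name Cell Ranger, the 10x software that assembles receptor contigs for each barcode, and its version and segment reference are not given in the sources used here. The deposited tables hold, for each assembled contig of a called cell, the counts of reads and UMIs, the V, D, J and constant segments, the CDR3 sequence and whether the contig is productive. Another deposited column, the contig length in nucleotides, was not used for any value. No value was normalized before deposit as far as the files show, and no genome build was given, so no coordinates are printed.

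The libraries were grouped by their titles as knock-in (KI, n = 2) and wild type (WT, n = 2), because the strain label names the knock-in allele for all 4 libraries. Nothing in the labels says that the replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The 4 tables held 55036 contigs of 17958 cells, of which 26243 contigs were productive with a TRG or TRD chain. A contig was called TRD where a TRDJ segment stood with a TRAV or TRDV segment, and TRG where a TRGJ segment stood with a TRGV segment. The TRD rule also kept contigs that the chain column lists as mixed, which were read in 160 and 371 cells of the WT libraries. Each cell gave 1 dominant productive contig per chain, the one with most UMIs. Doublets were not called, because the tables hold receptor contigs only.

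Cells per TRDV segment, TRGV segment or TRGV segment with CDR3γ amino acid sequence were summed per library and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. The library size was the number of cells with the chain, with no further scaling, and features with at least 10 cells over the 4 libraries were tested. Benjamini-Hochberg adjusted p-values were read against 0.05. Segments shared 1 common dispersion, and CDR3γ sequences had a trended dispersion. Standard errors (SE) of log2 fold changes were derived from the F statistic. The other 9 values were compared with a two-sided exact permutation test over the 4 libraries, whose smallest possible p is 0.333 with 6 assignments, so that test cannot reach 0.05. Diversity was counted as the mean over 1000 seeded draws of 1210 cells with TRG or 1960 cells with TRD. Shares of single libraries have exact Clopper-Pearson 95% intervals, and a count of 0 among TRG or TRD chains is given with the share that 3 counts would make. Intervals and limits cover counting error only. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

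The tests, the groups, the named items and most alternatives were fixed before the data were examined. The text names every TRGV segment tested, every TRDV segment with at least 1% of cells in a library, and the 5 most frequent TRGV and TRDV pairs per group. It also names CDR3γ sequences past the threshold and present in both libraries of the higher group, up to 10 per direction, the 3 most frequent CDR3 sequences of each library and chain, and the invariant sequences whatever their values. Alternatives were TMM factors, DESeq2 1.42.0, no minimum number of cells, the replicate number as a block, each library left out, contigs with at least 3 UMIs, cells with exactly 1 chain of each kind, distinct nucleotide sequences, every productive contig, and removal of cells that share a barcode and CDR3 with another library. Alternatives chosen after seeing the data were the deposited chain column, V and J segments that belong together, WT cells with any DV6 family segment, removal of TRGV6 cells, the CDR3γ counted from the second cysteine, cells thinned to 4 TRG UMIs, second TRG shares weighted to the same distribution of dominant TRG contig UMIs in each library, removal of TRGV1 to TRGV3 contigs, and crossed replicate numbers.

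The edgeR steps were tested on simulated cell counts drawn from the observed shares and library sizes in 33 simulations per fold. With TRGV6 changed among 7 segments at a dispersion of 0.008, it was recovered in 48.5% of simulations at 1.5-fold, 84.8% at 2-fold and 100% at 4-fold, while unchanged segments made up 5.9%, 17.6% and 15.4% of the calls. These shares pool the calls of all simulations and are not the error rate that the adjustment controls. They leave open whether the adjusted p of a TRGV segment is too small, and a TRGV call may be of an unchanged segment. With 12 CDR3γ sequences changed at a dispersion of 0.02, 7.3% were recovered at 2-fold, 74.7% at 4-fold and 98.5% at 8-fold, while unchanged sequences made up 9.4%, 4.5% and 3.5% of the calls. Changes of 2-fold in single CDR3γ sequences were therefore mostly below what 2 libraries per group can show.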

Results

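Productive TCRγ and TCRδ transcripts were read in single γδ T cells from the spleens of mice with a prearranged TCRδ chain inserted in the Tcrd locus (KI, n = 2 libraries) and of wild-type mice (WT, n = 2). The KI libraries held 4375 and 2253 cells and the WT libraries 3230 and 8100 cells. UMI totals were 39930 and 18857 in KI and 31964 and 69269 in WT. A productive TRG chain was read in 2288 and 1352 KI cells and in 1726 and 3441 WT cells, and a productive TRD chain in 3991 and 2186 KI cells and in 3158 and 7184 WT cells. The median dominant TRG contig had 2 UMIs in each library. Productive αβ receptor contigs were found in 1 cell of KI replicate 1 and 1 cell of WT replicate 2, and productive immunoglobulin contigs in 0 cells of every library. The primers targeted the TCRγ and TCRδ constant regions, so these counts set no limit on the share of αβ T cells or B cells.

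The first comparison asked whether KI cells carried the inserted chain, which was taken to be the most frequent TRD chain of the KI libraries. It was not compared with a known inserted sequence, so its identity with the inserted chain is inferred. The most frequent TRD chain of the KI libraries joined TRAV15D-1/DV6D-1, a V segment shared by the TRA and TRD loci, to the CDR3δ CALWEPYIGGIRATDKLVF. This nucleotide sequence was carried by 3991 of 3991 TRD cells in KI replicate 1 (95% interval 99.9 to 100%) and by 2185 of 2186 in KI replicate 2 (99.7 to 100%). The remaining KI cell had the base change C45A, counted from 1 at the first base of the CDR3, which gives D15E, and this contig had 2 UMIs. In WT, 1 of 3158 TRD cells carried the nucleotide sequence (0.0317%, 95% interval 0.000802 to 0.176%) in replicate 1 and 0 of 7184 in replicate 2, which allows a share of up to 0.0418%. The same CDR3δ amino acid sequence was carried by 0.0950% of TRD cells in WT replicate 1 and 0.0418% in WT replicate 2. By nucleotide sequence the group means were 99.98% ± 0.0323 in KI and 0.0158% ± 0.0224 in WT (SD, n = 2 each, exact permutation p = 0.333, the smallest possible).

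In WT cells the TCRδ repertoire was spread over many V segments. The DV6 family held 25.5% ± 0.390 of TRD cells, the DV7 family 25.3% ± 3.43, TRDV5 20.0% ± 1.74, TRDV2-2 14.7% ± 1.88 and TRDV1 8.94% ± 0.465 (SD, n = 2). The families DV12, DV8 and TRDV4 held 1.64%, 1.15% and 1.05%. None of these segments but TRAV15D-1/DV6D-1 was read in the 6177 KI cells with TRD, which allows a group share of up to 0.0486% for each. Against that limit, TRAV13-4/DV7 was at least 469-fold lower in KI, TRDV5 at least 413-fold, TRDV2-2 at least 302-fold, TRAV15D-2/DV6D-2 at least 252-fold, and TRAV15N-1 and TRDV1 at least 184-fold. TRAV15-1/DV6-1 was at least 84.5-fold lower, TRAV13D-2 at least 35.9-fold, TRAV21/DV12 at least 33.8-fold, TRDV4 at least 21.5-fold and TRAV16N at least 18.7-fold. TRAV15D-1/DV6D-1 rose from 0.149% ± 0.0135 in WT to 100% in KI (log2 fold change 9.40, SE 0.09, adjusted p = 1.09e-05, edgeR quasi-likelihood test). Of 22 segments tested, 1 was higher and 17 were lower in KI. The number fell to 1 with distinct CDR3δ nucleotide sequences counted in place of cells. Without WT replicate 1 or without WT replicate 2 there were fewer calls. Only 1 WT library was left there, so the spread within WT could not be estimated, and the reason for the fewer calls was not tested. The count with distinct sequences is no check, because KI held almost no distinct CDR3δ sequences and lower segments could not be called. With TMM factors the TRAV15D-1/DV6D-1 call ended (log2 fold change 0.04) and 21 segments were called lower.

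The TRGV comparison asked which γ chains accompanied the fixed δ chain. All 7 TRGV segments were used in KI. TRGV6, whose chain in fetal γδ T cells is largely invariant, rose from 3.13% ± 0.0750 of TRG cells in WT to 5.62% ± 0.102 in KI (SD, n = 2 each), a log2 fold change of 0.84 (SE 0.12, edgeR adjusted p = 0.00724). TRGV2, the most frequent segment, held 44.9% ± 1.70 in KI and 46.8% ± 2.05 in WT. TRGV4 held 24.4% ± 3.61 and 28.9% ± 0.366, and TRGV1 held 20.2% ± 4.47 and 14.8% ± 1.16. The edgeR log2 fold change was 0.44 (SE 0.18, adjusted p = 0.139) for TRGV1 and -1.32 (SE 0.54, adjusted p = 0.139) for the rare TRGV5. TRGV2, TRGV3, TRGV4 and TRGV7 had log2 fold changes of -0.06, -0.25, -0.24 and -0.43, and none passed the edgeR threshold. Constant-region clusters were assigned from the V segment alone. On that basis the TRGC1 cluster (TRGV4 to TRGV7) held 32.1% ± 3.10 in KI and 35.2% ± 1.15 in WT, and TRGC3 (TRGV3) 2.81% ± 0.321 and 3.25% ± 0.254. TRGC2 and TRGC4 equal TRGV2 and TRGV1 above. The J calls differed from this, with TRGJ3 at 0.755% in KI and 1.32% in WT and TRGJ4 at 25.2% and 19.9%. The cluster shares are therefore sums of V segments and not measured constant regions. The TRGV6 call ended without WT replicate 1 (log2 fold change 0.87), without WT replicate 2 (0.82) and with contigs of at least 3 UMIs (0.26), and in simulated data 17.6% of calls at 2-fold were of unchanged segments. With that UMI minimum the TRGV4 log2 fold change turned to 0.35, also below the threshold. With TMM factors TRGV1 was also called higher and TRGV5 lower, which gave 2 higher and 1 lower against 1 and 0, and without KI replicate 1 the 3 calls were TRGV1, TRGV4 and TRGV6. With distinct CDR3γ nucleotide sequences counted in place of cells, TRGV1 (log2 fold change 0.47) was also called higher and TRGV3 (-0.54) and TRGV4 (-0.43) lower, and in cells with exactly 1 chain of each kind TRGV1 (0.43) was also called higher. V and J segments belonged together in 85.4% to 92.1% of TRG cells per library. With only such contigs TRGV6 alone was called, and TRGV1 (0.42) and TRGV3 (-0.80) were not (edgeR adjusted p = 0.0988 and 0.107).

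**Figure D1:**
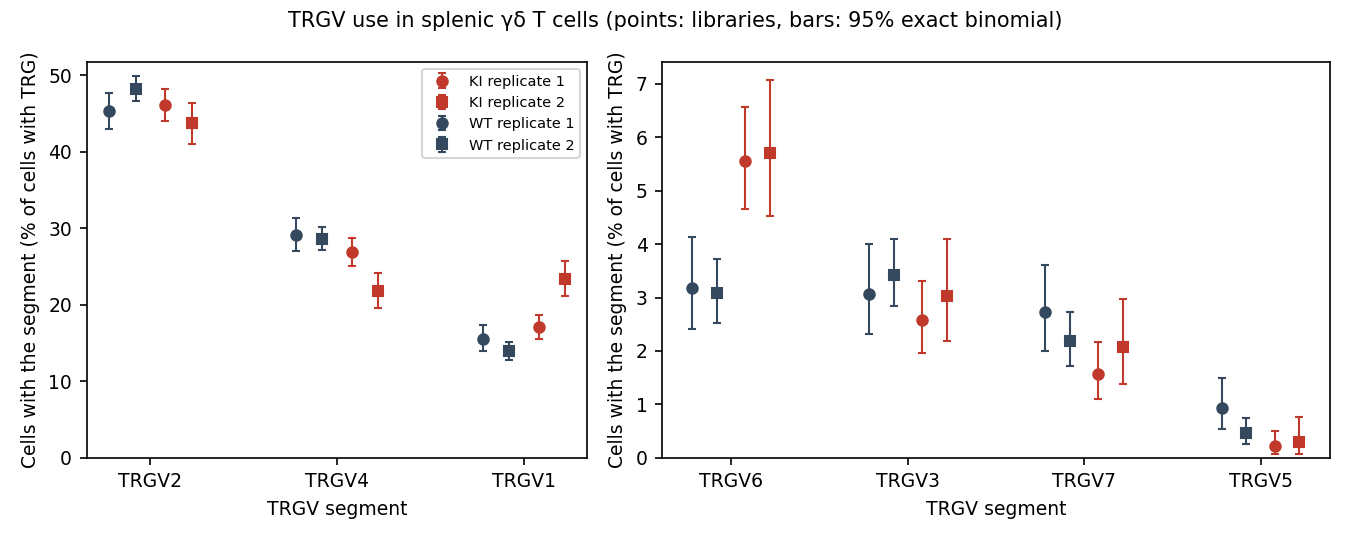
Share of cells with each TRGV segment, in percent of cells with a productive TRG chain, for the 2 KI and 2 WT libraries, with 95% exact binomial intervals as bars; the panels have different scales. TRGV6 lies at 5.55% and 5.70% in KI and at 3.19% and 3.08% in WT.

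A further comparison set KI cells against WT cells that use the knock-in V segment, to part the V segment from the fixed CDR3δ. Only 3 and 6 such WT cells had a TRG chain, and edgeR called 0 of 6 TRGV segments, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. Differences were not detectable at this depth. Against WT cells with any DV6 family segment, a comparison chosen after seeing the data, TRGV6 was higher in KI (log2 fold change 1.55, SE 0.27, edgeR adjusted p = 0.000411) and so was TRGV4 (0.60, SE 0.16, edgeR adjusted p = 0.00609). In the same comparison TRGV5 (-1.66, SE 0.58) and TRGV7 (-1.02, SE 0.28) were lower, and TRGV1 had a log2 fold change of -0.34 (edgeR adjusted p = 0.0597).

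The pairing of TRGV with Vδ segments was not uniform in WT cells. The most frequent WT pairs were TRGV4 with TRAV13-4/DV7 (12.2% ± 1.13 of paired cells), TRGV2 with TRDV5 (10.9% ± 0.0991), TRGV2 with TRAV13-4/DV7 (9.59% ± 1.54), TRGV2 with TRDV2-2 (6.42% ± 0.511) and TRGV4 with TRDV5 (5.62% ± 1.14; SD, n = 2). WT cells with a DV7 family segment used TRGV4 in 51.3% ± 1.56 and TRGV1 in 4.33% ± 0.260, whereas DV6 family cells used TRGV4 in 16.1% ± 0.0962 and TRGV1 in 25.8% ± 3.59. TRDV1 cells used TRGV1 in 30.2% ± 1.11, TRDV5 cells used TRGV2 in 54.0% ± 3.70, and TRDV4 cells used TRGV6 in 85.6% ± 5.08. In KI, where 1 δ chain was present, the 5 most frequent pairs joined it to TRGV2 (45.0% ± 1.55), TRGV4 (24.4% ± 3.76), TRGV1 (19.9% ± 4.27), TRGV6 (5.68% ± 0.291) and TRGV3 (2.83% ± 0.325).

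**Figure D2:**
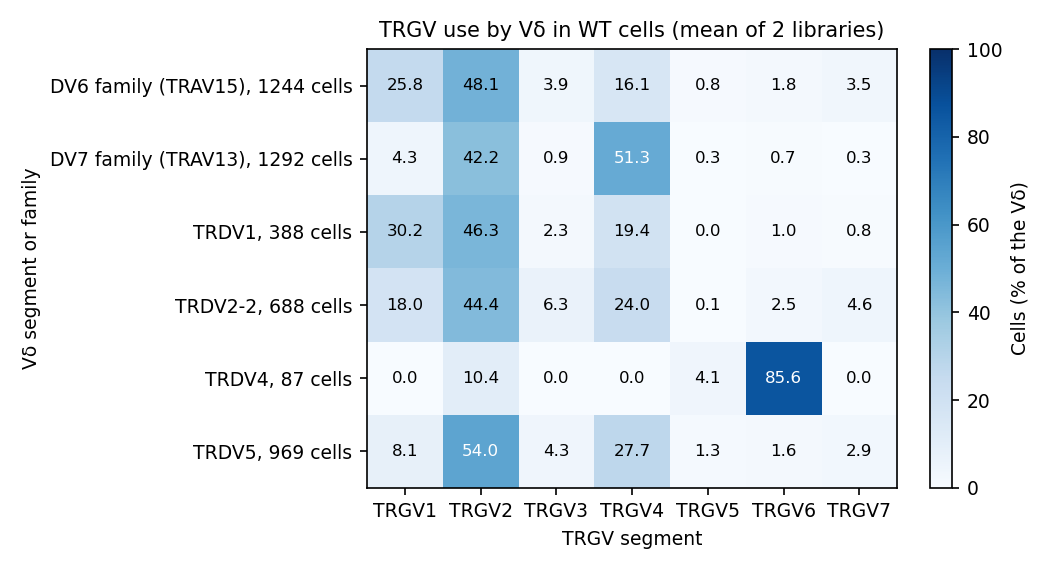
TRGV use among WT cells with each Vδ segment or family, as the mean of 2 libraries in percent of the cells with that Vδ; the number of cells is given with each name. TRDV4 cells used TRGV6 in 85.6% and DV7 family cells used TRGV4 in 51.3%.

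Single CDR3γ sequences differed between the groups within TRGV6 and TRGV4. TRGV6 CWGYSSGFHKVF was carried by 138 of 3640 KI cells and 3 of 5167 WT cells with TRG, a ratio of 65.3 (95% counting interval 21.9 to 321), with a log2 fold change of 5.89 (SE 0.35, edgeR adjusted p = 1.76e-05). TRGV6 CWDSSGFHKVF, the invariant junction without added bases, fell by 3.56 on the log2 scale (SE 0.43, edgeR adjusted p = 0.00203). Among TRGV6 cells, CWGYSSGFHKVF held 67.1% ± 3.08 in KI and 1.85% ± 0.0485 in WT, and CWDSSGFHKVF held 3.38% ± 2.56 in KI (1.57% and 5.19%) and 66.1% ± 9.40 in WT (SD, n = 2 each). TRGV4 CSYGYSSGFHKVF rose from 2.94% ± 0.178 of TRG cells in WT to 7.63% ± 1.38 in KI (log2 fold change 1.40, SE 0.22, edgeR adjusted p = 0.00965), and TRGV4 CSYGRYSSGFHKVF fell by 1.69 on the log2 scale (SE 0.31, edgeR adjusted p = 0.0184). Of 122 sequences tested, edgeR called 2 higher and 2 lower, each in the same direction in both libraries, and 21 had an unadjusted p under 0.05. The edgeR count was 8 in cells with exactly 1 chain of each kind, 0 without KI replicate 1 and 0 without KI replicate 2, 10 without WT replicate 1 and 8 without WT replicate 2. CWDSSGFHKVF had log2 fold changes of -2.76 without KI replicate 1 and -4.46 without KI replicate 2. The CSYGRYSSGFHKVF call ended with contigs of at least 3 UMIs (-0.74, edgeR adjusted p = 0.735, range over alternatives 0.000509 to 0.735). The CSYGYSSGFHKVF call ended with TMM factors, which gave 1 higher and 2 lower (edgeR adjusted p = 0.0526), and with no minimum number of cells, which gave 1 higher and 5 lower of 2585 (edgeR adjusted p = 0.708, the highest over its alternatives, the lowest being 1.65e-12 with DESeq2).

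**Figure D3:**
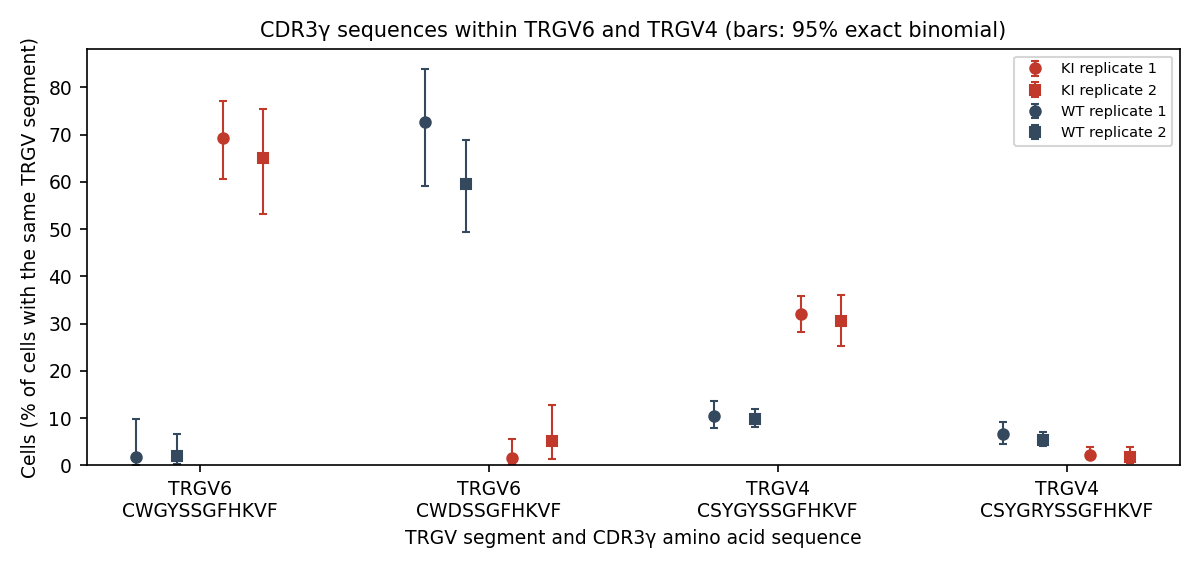
Share of 4 CDR3γ sequences, in percent of cells with the same TRGV segment, for the 2 KI and 2 WT libraries, with 95% exact binomial intervals as bars. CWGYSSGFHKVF lies at 69.3% and 64.9% of TRGV6 cells in KI and at 1.82% and 1.89% in WT.

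The most frequent CDR3γ of both KI libraries was TRGV4 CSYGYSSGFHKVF, at 8.61% (95% interval 7.49 to 9.84%) and 6.66% (5.39 to 8.12%), followed by TRGV6 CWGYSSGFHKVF at 3.85% (3.10 to 4.72%) and 3.70% (2.76 to 4.85%). The next sequence was TRGV4 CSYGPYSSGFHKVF at 1.57% (1.10 to 2.17%) in replicate 1 and TRGV1 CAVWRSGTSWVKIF at 2.07% (1.38 to 2.98%) in replicate 2. In WT the leading sequences were TRGV4 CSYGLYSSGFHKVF at 3.19% (2.41 to 4.13%) and 2.01% (1.56 to 2.53%), TRGV4 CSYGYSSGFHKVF at 3.07% (2.31 to 3.997%) and 2.82% (2.29 to 3.43%), and TRGV6 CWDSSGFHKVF at 2.32% (1.66 to 3.14%) and 1.83% (1.41 to 2.34%). The most frequent WT CDR3δ was TRDV4 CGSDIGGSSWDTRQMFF, the invariant δ junction, at 1.23% (0.880 to 1.68%) and 0.752% (0.565 to 0.980%). It was followed by TRDV5 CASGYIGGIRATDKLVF at 0.602% (0.363 to 0.938%) and TRDV2-2 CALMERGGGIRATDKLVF at 0.253% (0.109 to 0.499%) in WT replicate 1. In WT replicate 2 the next sequences were TRDV5 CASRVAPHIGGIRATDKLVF at 0.432% (0.293 to 0.612%) and TRAV13-4/DV7 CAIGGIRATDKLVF at 0.209% (0.117 to 0.344%).

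The invariant TRGV5 or TRGV6 junction was also taken as a fixed sequence, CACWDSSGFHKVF, which was found in 0 cells of every library because the deposited TRGV6 CDR3 starts at the second cysteine. Read from there, as chosen after seeing the data, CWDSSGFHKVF with TRGV5 or TRGV6 was carried by 0.229% ± 0.200 of KI (0.0874% and 0.370%) and 2.25% ± 0.426 of WT cells with TRG (SD, n = 2 each, exact permutation p = 0.333). Among WT cells with TRGV6 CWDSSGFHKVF and a TRD chain, 74.6% ± 10.5 paired it with TRDV4 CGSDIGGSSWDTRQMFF. TRDV5 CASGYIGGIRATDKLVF, the germline-like junction of interleukin-17 producing cells, was carried by 19 TRD cells of WT replicate 1 (0.602%) and 12 of WT replicate 2 (0.167%, 95% interval 0.0863 to 0.292%). It was found in 0 KI cells, which allows up to 0.0752% in KI replicate 1 and 0.137% in KI replicate 2.

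γ-chain diversity over all segments differed by less than the spread between libraries, while δ-chain diversity was almost absent in KI. Draws of 1210 cells held 750 ± 23.3 distinct CDR3γ nucleotide sequences in KI and 738 ± 21.7 in WT (SD, n = 2 each, exact permutation p = 0.667), and the difference turned to -4.64 without KI replicate 2 and -3.53 without WT replicate 1. By segment the differences went both ways, with 137 ± 4.70 sequences in KI and 159 ± 13.5 in WT among 265 TRGV4 cells, 338 ± 16.2 and 311 ± 5.48 among 530 TRGV2 cells, 182 ± 7.89 and 168 ± 8.01 among 240 TRGV1 cells, and 17.1 ± 0.117 and 14.4 ± 3.55 among 45 TRGV6 cells. Draws of 1960 cells held 1.45 ± 0.631 distinct CDR3δ sequences in KI and 1829 ± 21.7 in WT (exact permutation p = 0.333). The 10 most frequent CDR3γ sequences held 17.2% ± 1.24 of cells in KI and 14.7% ± 1.93 in WT (exact permutation p = 0.333), and with contigs of at least 3 UMIs the KI minus WT difference changed sign to -1.73 points. That difference was 2.51 points over all libraries, 1.63 without KI replicate 1, 3.87 without WT replicate 1 and 1.14 without WT replicate 2. The mean CDR3γ length was 13.88 ± 0.0194 amino acids in KI and 13.85 ± 0.0120 in WT (exact permutation p = 0.333), and the difference of 0.0259 ran from 0.0100 in cells with exactly 1 chain of each kind to 0.0664 with each sequence counted once. By segment, TRGV6 junctions were 12.1 ± 0.0679 amino acids long in KI and 11.6 ± 0.0865 in WT, and TRGV4 junctions 13.4 ± 0.0283 and 13.7 ± 0.0481. These lengths are not independent of the called sequences. Of TRGV6 cells, 67.1% in KI had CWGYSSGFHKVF and 66.1% in WT had the shorter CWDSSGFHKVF. Of TRGV4 cells, 31.2% in KI and 10.2% in WT had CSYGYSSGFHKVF, which is shorter than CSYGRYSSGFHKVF. The KI minus WT difference in mean length was 0.232 amino acids for TRGV1, 0.0992 for TRGV2 and -0.147 for TRGV3, each larger than the SD of either group, and 0.0476 for TRGV7, which was smaller.

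A second productive TRG chain was read in a larger share of cells in both KI libraries than in either WT library. It was present in 188 KI cells of replicate 1 and 125 of replicate 2, and in 90 and 158 WT cells, which made 8.73% ± 0.727 in KI and 4.90% ± 0.440 in WT (SD, n = 2 each, exact permutation p = 0.333). The KI minus WT difference of 3.83 points was 2.42 with libraries weighted to the same UMIs of the dominant TRG contig and 0.389 without TRGV1 to TRGV3 contigs. Without those contigs the shares themselves fell, to 0.725% ± 0.113 in KI and 0.336% ± 0.365 in WT. The difference was 6.55 in cells thinned to 4 TRG UMIs, which favoured cells with a second chain and left out 1584 and 936 KI and 1291 and 2713 WT cells. These 3 settings were chosen after seeing the data. A second productive TRD chain of different CDR3 was read in 63 and 272 WT cells, 1.99% and 3.79%, and in 0 cells of either KI library, which allows up to 0.0752% in replicate 1 and 0.137% in replicate 2. In KI this limit covered only a chain other than the inserted one, because 2 copies of the inserted chain, or 2 KI cells in 1 droplet, would be read as 1 chain, so the shares of KI and WT were not comparable. The median dominant TRD contig had 4 UMIs in both KI libraries and 6 and 4 UMIs in the WT libraries (exact permutation p = 1).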

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

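Of the alternative values for the compared results, 93 stayed within 1.5 times the count or within the spread between libraries, 37 moved by more and 1 difference between groups that did not overlap changed sign. The other sign was also seen for 2 of the 93, both of CDR3γ diversity. Some of the 93 could hardly move and show no stability. These are the counts of 0 against the 3 and 6 WT cells with the knock-in V segment, and the shares of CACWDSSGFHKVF, which cannot match the deposited CDR3γ. The count of TRDV segments was 1 with the replicate block and 1 with distinct nucleotide sequences, and ran from 1 to 18 with each library left out. With distinct sequences that count was fixed by the design, since KI held almost no distinct CDR3δ sequences. TMM factors and DESeq2 left TRAV15D-1/DV6D-1 at 0.04 and 1.15e-06 and called 21 other segments lower, since this segment, the only one read in all 4 libraries, sets their scale. The count of TRGV segments was 3 with TMM factors, 0 with the replicate block (TRGV6 log2 fold change 0.84, edgeR adjusted p = 0.0526, range over alternatives 1.08e-08 to 0.287), 0 with contigs of at least 3 UMIs, 2 in cells with 1 chain of each kind, 4 with distinct nucleotide sequences, 0 without TRGV6 cells, and 0 to 3 with each library left out. Against WT cells with any DV6 family segment the count was 4, where TRGV7 turned to -1.02 and TRGV2 to -0.10. The main comparison had only 3 and 6 WT cells, so the sign of its log2 fold changes moved freely: TRGV1 turned to 0.81 with TMM factors and 0.13 with distinct sequences, TRGV7 to -1.19 with DESeq2, TRGV3 to 6.06 and TRGV2 to -0.22 with at least 3 UMIs, TRGV2 to -0.0013 with every productive contig, and TRGV4 to -0.042 in cells with 1 chain of each kind and -0.16 with distinct sequences. With each library left out they ran from -0.73 to 0.27 for TRGV1, -0.57 to 12.09 for TRGV2, -3.58 to 8.08 for TRGV3 and -0.45 to 0.55 for TRGV4. The count of CDR3γ sequences was 7 with the replicate block, 8 in cells with 1 chain of each kind and 0 to 10 with each library left out. With crossed replicate numbers edgeR called 1 TRGV segment and 1 CDR3γ sequence. Libraries with the same number did not deviate together, at a correlation across features of -0.583 for TRGV and -0.207 for CDR3γ, so the numbers were not taken as pairs. TRGV6 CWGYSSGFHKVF had log2 fold changes from 5.26 to 6.04 over its alternatives, with adjusted p up to 0.0743. Its call ended only in the fits that left out a KI library. Among named segments and sequences, 199 alternative values kept their direction and their side of the threshold, 18 fell below it, 10 passed it and 20 had the other sign. The 199 include values against the 3 and 6 WT cells with the knock-in V segment, which could hardly pass the threshold and show no stability. For KI against all WT cells, TRGV2 turned to 0.0068 with DESeq2 and 0.062 with distinct nucleotide sequences, and TRGV4 to 0.35 with at least 3 UMIs, none of them past the threshold.

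CDR3γ diversity differed by -4.64 without KI replicate 2 and -3.53 without WT replicate 1 against 11.8 over all libraries. The KI minus WT difference was 99.9 points for the knock-in CDR3δ by amino acid sequence. For CDR3δ diversity it was -1458 with at least 3 UMIs, -1019 in cells with 1 chain of each kind, -1811 by amino acid sequence and -937 with 980 cells drawn, where the number drawn sets the scale. The share of the top 10 CDR3γ sequences changed sign to -1.73 points with at least 3 UMIs. With each library left out that difference ran from 1.14 to 3.87 points against 2.51 over all libraries, and the CDR3γ length difference from 0.0122 to 0.0396 amino acids against 0.0259. CDR3γ length differed by 0.0609 amino acids with at least 3 UMIs and 0.0664 with each sequence counted once. The invariant CDR3γ share differed by -2.02 points when read from the second cysteine. The second TRG share differed by 3.05 points with at least 3 UMIs and 2.42 weighted to equal dominant contig UMIs. The difference was 6.55 with cells thinned to 4 UMIs, which favours cells with a second chain. Without TRGV1 to TRGV3 it was 0.389, where the shares themselves fell to 0.725% in KI and 0.336% in WT. Without single libraries the second TRD share, which cannot show 2 copies of the inserted chain in KI, differed by -3.79 to -1.99 points and TRD UMIs by -2 to 0. Where no construction is named, the cause was not tested.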

Other observations

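The end GYSSGFHKVF, which the 2 sequences that rose in KI share, was measured in every TRGV segment after those sequences had been seen. In TRGV4 its first G lies in the start CSYG of nearly all tested sequences, whereas in TRGV6 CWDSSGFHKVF no G follows CW. The end was thus compared as letters and need not be the same junctional feature in each segment. Among TRGV4 cells it ended 33.6% ± 1.44 of CDR3γ in KI and 14.5% ± 0.281 in WT, and among TRGV6 cells 68.9% ± 3.83 and 3.70% ± 0.0970 (SD, n = 2 each). Among TRGV2 cells it ended 9.17% ± 1.24 and 8.20% ± 1.85, among TRGV7 cells 19.6% ± 7.58 and 15.3% ± 8.45, and among TRGV1 cells 1.56% ± 0.0310 and 0.684% ± 0.0838. The rarer TRGV3 had 0.847% ± 1.20 in KI and 0% in WT, and TRGV5 10.0% ± 14.1 and 3.12% ± 4.42. TRGV6 cells with neither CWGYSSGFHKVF nor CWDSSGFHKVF made up 1.66% ± 0.0594 of TRG cells in KI and 1.00% ± 0.269 in WT. The most frequent nucleotide form of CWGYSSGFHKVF was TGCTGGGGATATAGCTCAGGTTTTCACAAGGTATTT, in 71 of 88 and 42 of 50 KI cells and in all 3 WT cells.

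WT δ chains with the knock-in end YIGGIRATDKLVF were carried by 49 TRD cells of replicate 1 (1.55%) and 73 of replicate 2 (1.02%). TRGV2 was joined to TRGJ4, the J segment of another cluster, in 8.53% and 17.4% of TRGV2 cells in KI and in 10.6% and 7.77% in WT. Barcodes shared by both KI libraries numbered 14, of which 11 carried the knock-in CDR3δ in both, and 0 barcodes shared a CDR3γ between any of the 4 libraries.

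All the tests of explanations below were chosen after the results they bear on had been seen, except that the setting of at least 3 UMIs was fixed beforehand and the prediction for the weighted share was written before its value was computed.

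TRGV6 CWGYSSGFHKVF and TRGV4 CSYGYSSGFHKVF were more frequent in KI. Expansion of 1 clone for each sequence is not favoured as the whole cause, because the most frequent nucleotide form held at most 84.0% of the cells of either sequence in a KI library (upper 95% limit 92.8%), although several expanded clones remain possible. Free RNA is not favoured for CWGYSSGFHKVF, whose log2 fold change was 5.26 (SE 0.58) with contigs of at least 3 UMIs. Of its KI cells, 48.9% and 66.0% reached that minimum. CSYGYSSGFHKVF also stayed higher there (1.22, edgeR adjusted p = 0.0446). However, only 18.3% and 14.4% of its KI cells and 18.9% and 13.4% of its WT cells reached the minimum. Whether its cells with fewer UMIs held free RNA could not be judged in this way. The hypothesis that the fixed δ chain may raise this end alike in every segment was not borne out for TRGV2, which differed by 0.965 points and reached 9.17% in KI where the TRGV4 ratio of 2.31 would give 19.0%, although TRGV1 had a ratio of 2.28, close to that of TRGV4. Whether WT δ chains with the knock-in end pair more often with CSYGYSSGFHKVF stays open, since the libraries went opposite ways, 5.77% (3 of 52) against 2.53% in replicate 1 and 1.10% (1 of 91) against 1.57% in replicate 2, a mean difference of 1.38 points, and selection by the fixed δ chain within TRGV4 and TRGV6 remains an untested biological hypothesis.

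A second TRG chain was read in a larger share of KI cells. Depth per cell may explain part of it. With each library weighted to the same UMIs of the dominant TRG contig, the shares were 7.90% ± 0.519 in KI and 5.48% ± 0.0745 in WT. The difference was 2.42 points against 3.83 unweighted, so the depth equalized in this way did not explain all of it. Cells with 5 or more such UMIs were weighted as a single class. Depth within that class was not equalized and may explain more. Droplets with 2 cells are not favoured by the comparison with WT replicate 2, as both KI libraries held fewer cells and the lower of them still exceeded it by 3.63 points. However, KI replicate 1 held more cells than WT replicate 1, 4375 against 3230. In WT replicate 2 a TRG chain was read in 44.6% of TRD cells, the lowest share of any library. A second chain may be missed more often there, and the 3.63 points were not corrected for this. Assembly between the near-identical TRGV1, TRGV2 and TRGV3 cannot be told apart from a real second chain, since few cells remained without them. The shares were then 0.805% and 0.645% in KI and 0.594% and 0.0782% in WT, a mean difference of 0.389 points. Both groups fell, so the smaller difference does not show that the excess ended with these segments. A biological difference between KI and WT, such as retention of cells with 2 γ chains, stays among the open explanations.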
